A study of Drosophila melanogaster with 4 samples.

How the data were processed

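Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K27me1, the monomethylated form of lysine 27 of histone H3, in nuclei from the heads of adult wild-type Oregon-R flies (Drosophila melanogaster). Per the labels' protocols, flies were kept in population cages on a 22-day adult cycle, heads were separated with sieves, chromatin was fixed with formaldehyde and sonicated, and the antibody (Millipore) was incubated with the chromatin for 15 hours. The series holds 4 libraries, 2 H3K27me1 ChIP replicates and 2 Input libraries, and per the labels each Input served as the input for the list of 1 ChIP replicate. Nothing in the labels says whether the replicates came from separate collections of flies, so differences between them may be technical. The p-values here compare the clusters of these lists with shifted, randomly placed or permuted ones. They measure no spread between libraries.

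The deposited files are 3 lists of enriched regions, called clusters here: 1 for each ChIP replicate and 1 for the set of both replicates, which is given as the authors' own list with no n or SD. No list of the Input libraries was used here. Per the file headers, coordinates are those of FlyBase release 5 of the fly genome, and each line describes a region of significant enrichment with a start, an end and 1 score. Bowtie 0.12.7, a short-read aligner, was used per the submitters' processing notes. The cluster caller, its threshold, its filters and the way the replicates were combined are not given in the sources used here. Each score is the authors' own value per cluster and carries no stated unit in the deposited files. Its scale was read from the values. Among the 20 highest distinct scores of replicate 1, 51.6% of the 190 pairs differed by the base-2 logarithm of a ratio of whole numbers with a denominator of at most 50, within a relative tolerance of 1e-06. For replicate 2 the share was 52.1%, and for the replicate-set list it was 85.4% of 171 pairs. With a natural logarithm the share was 0% in both replicates, and with a base-10 logarithm it was 2.63% and 5.26%. The scores are therefore read as log2 ratios of read counts, and folds below are 2 raised to the score. A constant added to all scores of a list would cancel in these differences, so the folds hold only if none was added. Whether a score is a mean or a maximum over its cluster was not settled.

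Read counts and sequencing depth are not part of the lists, so the depth behind each cluster is unknown and no counting interval on the enrichment can be given. The narrowest cluster was 1301 bp in both replicate lists and 1001 bp in the replicate-set list. All starts in the replicate-set list are even numbers, against 48.9% and 50.4% of starts in the replicates. A cluster end past the sequence length in the header was found once in replicate 2 and once in the replicate-set list, and such ends were set to the sequence length for overlaps and covered lengths. Chromosome lengths were taken from the file headers, in place of the end of the last cluster that had been planned for a case without a matching genome. The gene table at hand is of genome release 6, so no gene was assigned to a release 5 coordinate. The planned analyses of annotated features and gene lists were not run, and regions are named in place of genes.

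All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A cluster counted as shared where at least 1 bp lay in a cluster of the other list. Overlap was compared with 10000 random circular shifts of one list within each chromosome, which keep cluster widths and spacing, in a one-sided test whose smallest possible p is 0.0001. Scores were compared over pairs in which 1 cluster of each replicate overlapped only the other, and p came from a permutation test with 100000 resamples (smallest possible p, 1e-05). Widths and scores of shared and replicate-only clusters were compared by their medians in a two-sided permutation test with 100000 resamples, as planned (p = 1e-05 for all 4 differences). That test ignores that wide clusters overlap more often by chance, so the differences were also computed under 10000 circular shifts, and those are reported. Shares of chromosome arms have 95% intervals from 2000 bootstrap draws of 1 Mb blocks (250 kb for chromosome 4 and the heterochromatic scaffolds). Intervals on shares of clusters are exact binomial. A label permutation between 2 samples and 2 samples cannot go below a two-sided p of 0.333, so no test across libraries was used, and clusters and blocks within a library are not biological replicates. Where p-values were adjusted, the Benjamini-Hochberg method was used; the other families hold equal p-values, which that adjustment leaves as they are. A simulated list of 6365 clusters was set against a copy that kept 59.8% of them. The share found was 59.8%, as it had to be, so this checks only the counting. Of 20 pairs of independent simulated lists, 2 gave p under 0.05, with fewer shifts than in the main test. Those lists were placed at random, without the runs of clusters seen in the data, so they do not test that setting.

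The rule for named regions was the 10 widest and the 10 highest-scoring clusters of the replicate-set list that overlap a cluster in both replicates, the widest such cluster on each sequence, and the widest gap on each arm. Alternatives were an overlap of at least 50% of the cluster or of both clusters, the upper 50% of each list by score, a minimum width of 1000 bp, merging across gaps under 1000 bp, the major arms alone, random placement in place of shifts, 250 kb blocks, arm lengths from the first to the last cluster, and each replicate alone. The designs, rules and these alternatives were set before the data were examined. A common score minimum on all arms, a width minimum on the replicate-set list and sharing by the midpoint of a cluster were added afterwards, as were the shifts for shared clusters, the spacing tests, the comparison of covered length between replicates by chromosome, and the arm-end values.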

Results

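The study mapped H3K27me1 in adult fly heads with 1 antibody and no second condition. The comparisons it implies are therefore between the 2 ChIP replicates, between the replicates and the authors' list for the replicate set, and between parts of the genome. H3K27me1 is a methylation state of the lysine that the Polycomb enzyme E(z) modifies. The clusters are the authors' regions of significant enrichment, and the depth of the libraries is unknown.

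H3K27me1 clusters covered a minor part of the major chromosome arms (2L, 2R, 3L, 3R, 4 and X), at 19.4% ± 0.633 (SD, n = 2). Replicate 1 held 6501 clusters over 24.5 Mb, and replicate 2 held 6601 clusters over 23.3 Mb. The mean number of clusters was 6551 ± 70.7 (SD, n = 2). Most clusters were a few kilobases wide, with a median width of 2700 bp in replicate 1 and 2581 bp in replicate 2. Broad domains of 10 kb or more numbered 303 in replicate 1 and 235 in replicate 2, and held 17.4% and 13.7% of the covered length. The authors' score per cluster had a median of 0.72 in both replicates. On the log2 scale read from the values this would be a 1.65-fold and a 1.64-fold enrichment, if no constant was added to the scores. Wider clusters scored higher, with a Spearman rho between width and score of 0.734 in replicate 1 and 0.705 in replicate 2, computed across clusters, which are not independent.

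The clusters lay in runs along the arms. The median gap between neighbouring clusters on the major arms was 3741 bp in replicate 1, and 21.9% of gaps were under 1 kb. When clusters of the same widths were placed at random along each arm, the mean share of such gaps was 6.45%, and none of 1000 placements exceeded 7.49%. In replicate 2 the median gap was 3662 bp and 21.8% of gaps were under 1 kb, against a mean of 6.63% at random. Both observed shares lay above all random placements run (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Short gaps can also come from a domain called in pieces, and this was not separated from runs of distinct clusters. The widest domain, on 3L, was 1 cluster in replicate 1 and 4 clusters in replicate 2.

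The first comparison asked whether both replicates marked the same regions. Of the replicate 1 clusters, 5222 of 6501 (80.3%) overlapped a replicate 2 cluster, and of the replicate 2 clusters, 5440 of 6601 (82.4%) overlapped a replicate 1 cluster. Circularly shifted clusters overlapped in 31.4% and 31.8% of cases on average, and no shift exceeded 42.3% and 43.4%. The lists shared 19.4 Mb, 4.14 times the 4.69 Mb expected from the shifts, which was 68.5% of the 28.3 Mb covered by either list. The p of the shift test was 0.0001 for both lists, the smallest that 10000 shifts can give. On the large autosomal arms the overlap was even. Between 83.7% (2L) and 86.4% (2R) of replicate 1 clusters were found in replicate 2. On the X the share was 62.4% (exact 95% interval 59.4% to 65.3%), and on chromosome 4 it was 62.5% (49.5% to 74.3%). In the other direction, 79.4% of the X clusters and 45 of the 49 chromosome 4 clusters of replicate 2 were found in replicate 1.

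Clusters seen in both replicates were broader and scored higher than those seen in 1. In replicate 1 the shared clusters had a median width of 3238 bp and the others 1616 bp, and the median scores were 0.76 and 0.62. In replicate 2 the median widths were 3009 bp and 1572 bp, and the median scores were 0.75 and 0.61. Wider clusters overlap more often by chance, and circular shifts gave mean width differences of 671 bp and 552 bp, against 1622 bp and 1437 bp observed. The mean score differences under shifts were 0.03 in both replicates, against 0.13 and 0.14. All 4 observed differences exceeded those of all 10000 shifts (one-sided permutation p = 0.0001, the smallest they can give). The score difference was not computed at equal width. Replicate 1 clusters on the large autosomal arms were split into 5 classes of width and of score (1 lowest). From score class 1 to 3, the share found in replicate 2 fell from 53.8% (of 626 clusters) to 43.4% (of 53) in width class 1. It fell from 77.7% (of 453) to 67.7% (of 124) in class 2 and rose from 87.5% (of 88) to 94.97% (of 378) in class 3. In class 4 it rose from 89.5% (of 19) to 96.9% (of 261), and in class 5 it was at least 99.3%. Score classes 4 and 5 held only 12 and 5 clusters in width class 1, and 16 and 5 in class 2. No interval was computed on these shares. In these counts a higher score did not go with more sharing at every width, but some of the classes are small.

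**Figure D1:**
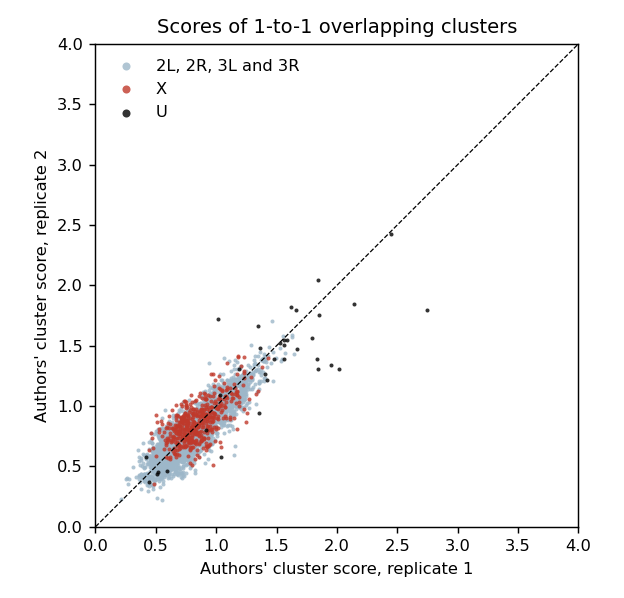
Authors' cluster score in replicate 1 (x axis) and replicate 2 (y axis), both read as log2 ratios, for clusters that overlap 1-to-1, with a point per pair. Points are coloured for the large autosomal arms, the X and the unplaced scaffold sequence U, the dashed line marks equal scores, and over all 3964 pairs Spearman's rho was 0.837.

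The height of the enrichment was ranked alike in both replicates. Over 3964 clusters that overlapped 1-to-1, Spearman's rho between the scores was 0.837 and Pearson's r was 0.867 (permutation p = 1e-05 for both, across clusters). The median difference, replicate 2 minus replicate 1, was -0.01 with an SD of 0.12 between pairs. The widths of the same pairs had a rho of 0.838, and with both widths held the rho between the scores was 0.685. The X pairs scored higher than the pairs of the large autosomal arms in both replicates, with medians of 0.82 against 0.75 in replicate 1 and 0.85 against 0.74 in replicate 2, a difference that was not tested.

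The distribution over chromosomes compared the share of each arm lying in clusters. The large autosomal arms were covered to 21.1% (95% block interval 19.7% to 22.4%) in replicate 1 and 20.8% (19.5% to 22.1%) in replicate 2. Arm 2L was the least covered of them, at 18.7% and 18.2%, and 2R the most, at 23.1% and 23.0%, with intervals that overlap in replicate 1 (16.3% to 21.4% and 21.1% to 25.02%) and not in replicate 2 (15.9% to 20.8% and 21.0% to 25.1%). The X was covered to 14.7% (12.9% to 16.6%) in replicate 1 and 11.3% (9.61% to 12.9%) in replicate 2. The ratio of the X to the autosomal share was 0.700 (0.603 to 0.800) in replicate 1 and 0.540 (0.457 to 0.630) in replicate 2, a mean of 0.620 ± 0.113 (SD, n = 2). The intervals exclude equal coverage in both replicates. They describe variation along the genome within a library. X clusters were narrower, with medians of 2216 bp and 2061 bp against 2862 bp and 2684 bp on the autosomal arms. The number of X clusters per Mb was 0.895 times the autosomal number in replicate 1 (0.779 to 1.01) and 0.702 times in replicate 2 (0.599 to 0.810). Among the upper 50% of clusters by score this order turned, to 1.26 times in both replicates, while the X stayed less covered in the replicates, at 0.807 and 0.718 times the autosomal share. X clusters had higher scores, with medians of 0.77 and 0.84 against 0.70 and 0.69 on the large autosomal arms. A score cut over the whole list therefore keeps a larger share of them, and the turn in numbers follows from that.

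**Figure D2:**
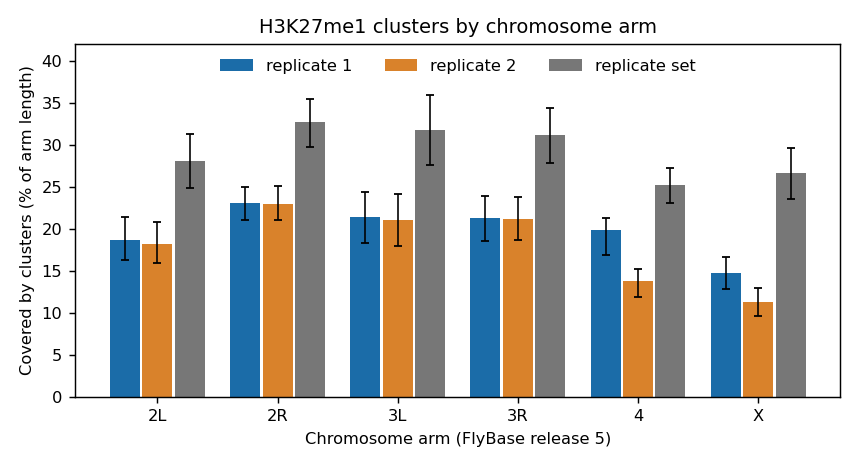
Share of each chromosome arm covered by H3K27me1 clusters (y axis, percent of arm length from 0), for replicate 1, replicate 2 and the authors' replicate-set list. Error bars are 95% bootstrap intervals over 1 Mb blocks (250 kb for chromosome 4), and the X bars of the replicates, at 14.7% and 11.3%, are the lowest except for chromosome 4 in replicate 2 (13.8%), which lies between them.

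Chromosome 4, the small dot chromosome with largely heterochromatic properties, was covered to 19.9% in replicate 1 and 13.8% in replicate 2. The heterochromatic scaffolds (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) were covered to 3.90% (1.98% to 6.35%) and 3.14% (1.45% to 5.32%), below any of the arms. YHet, from the Y chromosome, held no cluster in replicate 1 and 1 cluster of 1384 bp in replicate 2. The unplaced sequence U was covered to 1.66% and 1.28%, and Uextra held no cluster in any of the 3 lists. Clusters on U had the highest scores of any sequence class, with medians of 1.57 in replicate 1 and 1.5 in replicate 2. Whether reads can be aligned uniquely to the scaffolds, U and Uextra was not examined. Neither their low coverage nor the high scores on U can therefore be read as a level of H3K27me1.

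The replicates differed in covered length on some chromosomes and hardly on others. On the X the length in replicate 2 was 0.763 times that in replicate 1 (95% block interval 0.724 to 0.807), and it was lower in 23 of 23 blocks of up to 1 Mb. On chromosome 4 the ratio was 0.693 (0.629 to 0.767), on the heterochromatic scaffolds 0.805 (0.685 to 0.877) and on U 0.769 (0.617 to 0.886). Chromosome 4 holds only 6 blocks of 250 kb and U 11 blocks of 1 Mb, so their intervals rest on few blocks and may be too narrow. On the large autosomal arms the ratio was 0.990 (0.979 to 1.00), with 55 of 99 blocks lower in replicate 2. By arm it ran from 0.974 (0.956 to 0.993) on 2L to 0.997 (0.969 to 1.02) on 2R. The X ratio relative to these arms was 0.771 (0.730 to 0.816).

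Within arms, H3K27me1 coverage varied several-fold between 1 Mb blocks, and both replicates showed the same profile. Over the 95 full blocks of the large autosomal arms, coverage (mean of both replicates) ran from 6.27% to 38.5%, and Pearson's r between the replicates was 0.985, across blocks that are not independent. The most covered block was 3R 5000001 to 6000000, at 39.4% and 37.5% in the replicates, followed on 2L by 8000001 to 9000000, at 36.2% and 35.1%. The least covered was 3L 23000001 to 24000000, near the centromere, at 7.13% and 5.41%. On the X, 22 full blocks ran from 5.67% to 21.4% with an r of 0.937, and its most covered block by the mean of both replicates, 1000001 to 2000000, reached 21.8% and 21.0%. In replicate 1 alone the block 11000001 to 12000000 was covered more, at 24.5%, against 17.1% in replicate 2.

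**Figure D3:**
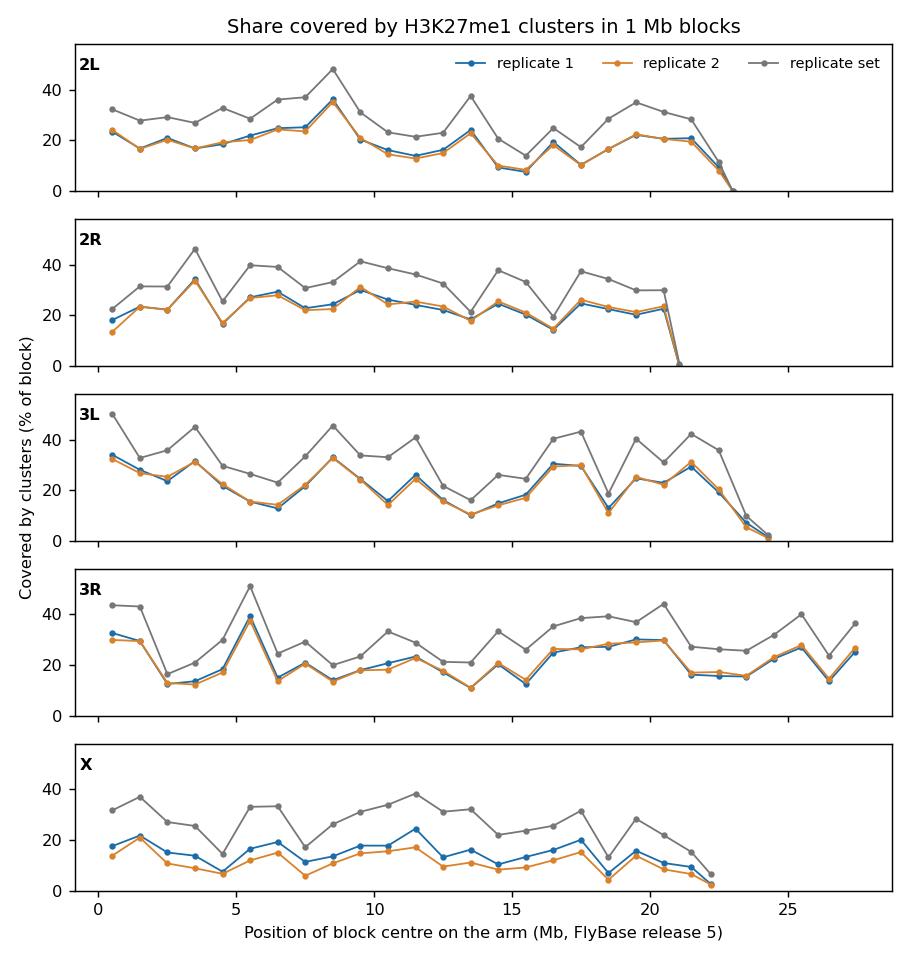
Share of each 1 Mb block covered by H3K27me1 clusters (y axis, percent) against the position of the block on the arm (x axis, Mb, FlyBase release 5), for replicates 1 and 2 and the replicate-set list. The last point of each arm is a block shorter than 1 Mb. The replicate lines lie on each other on the autosomal arms (r = 0.985 over full blocks), and on the X replicate 2 lies below replicate 1 in all 23 blocks.

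The authors' list for the replicate set was longer than either replicate list, with 9662 clusters over 37.0 Mb. It took in 99.7% of the clusters of each replicate, leaving out 17 of replicate 1 and 22 of replicate 2. Of its clusters, 4403 (45.6%, exact 95% interval 44.6% to 46.6%) overlapped both replicates, 1926 (19.9%) overlapped 1 replicate and 3333 (34.5%) overlapped neither. The clusters found in both replicates were the broad ones, with a median width of 4855 bp and 74.1% of the list's covered length. Those found in neither had a median width of 1333 bp and held 13.5% of the length. The X held 12.8% of the set's clusters found in both replicates and 24.4% of those found in neither. In this list the X was covered to 26.6% and the large autosomal arms to 30.9%, a ratio of 0.862 (0.752 to 0.971). Among the upper 50% of its clusters by score the order turned, to a ratio of 1.04 with an interval that includes equal coverage (0.896 to 1.19), while with a common score minimum of 0.67 on all arms it was 0.841 (0.702 to 0.988). The X clusters of this list scored higher (median 0.56 against 0.47 on the large autosomal arms), so the upper 50% holds a larger share of them. The 10th percentile of its scores was 0.36, against 0.53 and 0.52 in the replicates, so its covered length cannot be compared with theirs as a level.

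The widest H3K27me1 domain was a 54.6 kb cluster on 3L, from 17958426 to 18012986. Replicate 1 held it as a single cluster covering 99.0% of its length, and replicate 2 as 4 clusters covering 95.1%. Next came 2R 14167504 to 14219392 (51.9 kb), of which the replicates covered 86.3% ± 5.19 (SD, n = 2), and 2R 6369746 to 6416586 (46.8 kb), covered to 88.0% ± 3.86. On 3R the widest was 5827770 to 5868358 (40.6 kb), covered to 93.9% ± 1.15. The rule took only replicate-set clusters that overlap both replicates, and that list is for the set of the same replicates. The coverage of these domains is therefore no independent check of them. All 10 widest domains measured at least 38.1 kb, and 9 of them were covered to more than 50% in both replicates. The exception was the widest X domain, 11387332 to 11428932 (41.6 kb), covered to 78.7% in replicate 1 and 45.1% in replicate 2. The heterochromatic scaffold 2RHet held a domain of 41.1 kb, 3136382 to 3177472, covered to 90.2% ± 8.67, in a scaffold that was covered to 5.66% and 4.66% as a whole. The widest domain of 2L was 8626498 to 8668770 (42.3 kb, 74.9% ± 2.26), inside its most covered block. On chromosome 4 it was 111466 to 130284 (18.8 kb, 90.7% ± 5.73). The other scaffolds had narrower widest domains, from 9.32 kb on XHet to 22.0 kb on 3RHet. All 10 of the highest-scoring clusters found in all 3 lists lay on U, led by 6925268 to 6927642 with a set score of 2.48 and replicate scores of 2.45 and 2.43. Gene annotation of this genome release was not used here, so the genes in these domains are not named.

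Long stretches without H3K27me1 clusters were found on every major arm. The longest was on 3L, from 18173983 to 18611887 (438 kb), on the same arm as the widest domain. On 3R the longest ran from 2485787 to 2890111 (404 kb), on 2R from 2143233 to 2501081 (358 kb), on the X from 21503205 to 21849475 (346 kb), and on 2L from 1193023 to 1500389 (307 kb). Neither replicate list held a cluster in these stretches, except for 0.028 kb at the edge of the 2L stretch in replicate 1. With clusters placed at random, the widest gap on 3L averaged 69.2 kb and never exceeded 120 kb. The gaps on 2L, 2R, 3L, 3R and X exceeded all 1000 random placements (permutation p = 0.001, the smallest that 1000 placements can give, Benjamini-Hochberg adjusted p = 0.0012 over 6 arms), and that of chromosome 4, 86.1 kb, had an adjusted p of 0.026. Random placement does not keep the runs of clusters. In the replicate-set list 32.2% of gaps were under 1 kb, against a mean of 10.6% at random, and such runs leave longer gaps elsewhere. The p-values therefore do not show that these stretches are unusual beyond the runs. Whether reads can be aligned uniquely to these stretches was not examined.

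**Figure D4:**
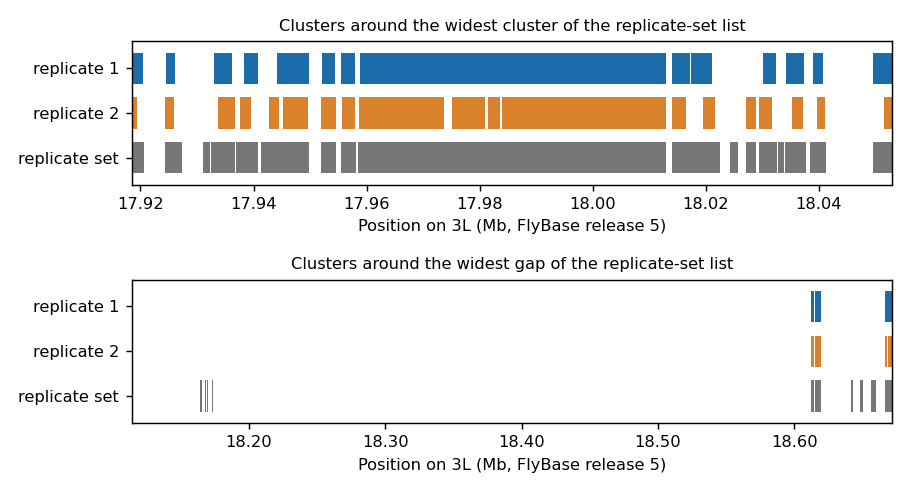
Clusters of replicate 1, replicate 2 and the replicate-set list as boxes to scale along 3L (x axis, Mb, FlyBase release 5), around the widest replicate-set cluster (top, 54.6 kb) and around the widest gap between replicate-set clusters (bottom, 438 kb). The replicates cover 99.0% and 95.1% of the domain, and the gap holds no cluster in any of them.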

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

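The common score minimum, the minimum width of replicate-set clusters and sharing by midpoint were chosen after seeing the data. A minimum width of 1000 bp removed no cluster and so tested nothing. The overlap of the replicates stayed above its random expectation in the settings of overlap, score, merging, arms and placement run for it. Spearman's rho of the scores, 0.837 in the main setting, was 0.851 for pairs sharing 50% of both clusters. It was 0.836 on the major arms and fell to 0.685 given width. The permutation p was 1e-05 in each setting, the smallest possible. The greater width and score of shared clusters held at 50% overlap, on the major arms and where the midpoint of the cluster had to lie in the other list. The lower covered share of the X in both replicates held for the upper 50% by score, 250 kb blocks, first-to-last cluster lengths and the common score minimum. The overlap of clusters averaged 81.4% over both lists and ranged from 66.0% (at least 50% of both clusters) to 81.8% (gaps under 1000 bp merged). The X to autosome ratio of covered share ranged from 0.699 to 0.807 in replicate 1 and from 0.539 to 0.718 in replicate 2. The ratio of clusters per Mb turned, to 1.26 in both replicates for the upper 50% by score and to 1.27 and 1.14 under the common score minimum. Both cuts keep a larger share of the X clusters of the replicates, which score higher. In the replicate-set list the upper 50% by score gave 1.04 for covered share and 1.78 for clusters per Mb, against 0.841 and 1.00 under the common score minimum, and the cause was not tested. By construction, keeping the upper 50% of clusters by score gave a mean of 3276 clusters and 16.7 Mb per replicate with a median width of 4119 bp, and merging across gaps under 1000 bp gave a median width of 3292 bp. The share of replicate-set clusters found in both replicates moved with several settings. It was 38.9% where 50% of the cluster had to be shared, 48.8% for the upper 50% by score, 51.9% after merging, and 55.2% for replicate-set clusters of at least 1301 bp. With either replicate left out, 55.0% to 56.0% of the replicate-set clusters overlapped the remaining one. No paired analysis was possible because the Input libraries have no values used here and nothing was tested between ChIP and Input. The alternatives for annotated features and gene lists were not run, since the gene table is of another genome release. Depth is unknown, so regions without a cluster cannot be called free of H3K27me1.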

Other observations

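The test of a common score minimum as the reason for the lower X coverage, the match on scores taken from the 10th percentile, the count of clusters found in 1 replicate and the comparison of low scores between classes of replicate-set clusters were chosen after the results had been seen, as was the minimum width of replicate-set clusters, and the arm-end values were computed without a plan.

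The ends of the arms differed from each other in H3K27me1 coverage. In the 1 Mb next to the centromere, coverage (mean ± SD of 2 replicates) was 1.91% ± 0.206 on 3L, 6.19% ± 1.58 on X, 8.69% ± 0.905 on 2L and 15.8% ± 3.28 on 2R. The inner parts of these arms were covered to 21.5% ± 0.145, 13.2% ± 2.5, 18.7% ± 0.361 and 23.6% ± 0.0950. On 3R the order was the opposite, with 31.3% ± 1.94 next to the centromere and 20.7% ± 0.0204 in the inner part. At the telomere end coverage was 33.1% ± 1.16 on 3L, 23.8% ± 0.522 on 2L, 23.8% ± 0.954 on 3R, 19.4% ± 0.541 on 2R and 15.7% ± 2.67 on X. The centromere-side value was lower in replicate 2 than in replicate 1 on 5 of 5 arms, the inner part on 4 of 5 and the telomere side on 2 of 5. The centromere-side mean over the 4 large autosomal arms was 15.5% in replicate 1 and 13.3% in replicate 2, a ratio of 0.856. The ratio was 0.993 in the inner parts and 1.01 at the telomere side. Whether reads can be aligned uniquely next to the centromeres was not examined.

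The X was less covered than the large autosomes in both replicates, and the 10th percentile of its scores was higher, by 0.09 (95% block interval 0.08 to 0.11) in replicate 1 and 0.15 (0.14 to 0.17) in replicate 2. A candidate explanation is that a call on the X needed more enrichment, as where fewer reads fall on the X of flies that include males. With a common score minimum of 0.67 on all arms, the X to autosome ratio of covered share was still 0.806 (0.691 to 0.925) in replicate 1 and 0.673 (0.568 to 0.793) in replicate 2, but that of clusters per Mb was 1.27 (1.10 to 1.43) and 1.14 (0.964 to 1.32), and since the minimum removes whole clusters and narrows none, this explanation stays open. For narrower X clusters alone, the replicates differed. Clusters per Mb stood at 0.895 times the autosomal number (0.779 to 1.01) in replicate 1, an interval that includes equal numbers. In replicate 2 the value was 0.702 (0.599 to 0.810), so the X also held fewer clusters there and narrower width alone does not account for its coverage. Over both replicates this explanation is not settled. No biological explanation was tested, as the design has no group that bears on one.

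On the X less length was covered in replicate 2 than in replicate 1, as on chromosome 4 and the heterochromatic scaffolds, whose joint ratio relative to the large autosomes was 0.765 (0.695 to 0.834). U also lost length, with a ratio of 0.769 (0.617 to 0.886) not taken relative to the autosomes. X clusters of replicate 1 were found in replicate 2 less often, by -14.7 percentage points (-19.1 to -10.2), than autosomal clusters in the same 5 classes of score and of width, and by -16.2 (-19.6 to -12.6) with scores taken from the 10th percentile of X or autosomes. A general lack of weak clusters in replicate 2 is argued against by these values and by the large autosomes, where 947 clusters were found only in replicate 2 and 798 only in replicate 1, a ratio of 1.19 (1.07 to 1.31), against 0.456 (0.369 to 0.557) on the X. A higher score limit on the X in replicate 2 was put to a rule written before its test. Under such a limit, the X ratio of covered length relative to the large autosomes would have an interval reaching equality with the common minimum. The ratio was 0.836 (0.791 to 0.884), so the rule went against this explanation. The ratio of cluster numbers was 0.897 (0.834 to 0.962). Removing whole clusters below that minimum therefore does not account for the whole loss. The minimum cannot mimic a limit that also narrows clusters, so a limit of that kind stays open. In 1-to-1 pairs the median width ratio, replicate 2 to 1, was 0.902 on the X and 0.994 on the large autosomal arms. The median score differences were 0.022 and -0.013. The share of males and differences between the Input libraries were not tested and stay open, and no biological explanation was tested.

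The replicate-set list held 3333 clusters found in neither replicate. Its lower minimum width is argued against as the whole reason, since 1774 of them were at least as wide as the 1301 bp minimum of the replicates. It goes with part of them, as 46.8% (exact 95% interval 45.1% to 48.5%) were narrower than that minimum. Among replicate-set clusters of at least 1301 bp, 22.3% were found in neither replicate, against 34.5% of the whole list. A lower score limit stays open: 84.5% (83.2% to 85.7%) of them scored below 0.53, the 10th percentile of the replicate lists, but so did 82.7% (80.9% to 84.4%) of the clusters found in 1 replicate and 56.1% of the whole list, against 22.8% of those found in both. In 3152 clusters found 1-to-1 in all 3 lists, the set score minus the mean of the replicate scores had a median of -0.08, and the cause was not tested. No biological explanation was tested.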
